A study of Mus musculus with 115 samples.

How the data were processed

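The series holds small RNA sequencing of mouse tissues and cells (RNAs shorter than 40 nt, isolated on gels from total RNA; mice of 10 to 12 weeks where an age is given). The authors' count table gives deposited counts of reads per annotated tRNA, miRNA, miRNA locus, piRNA cluster, repeat and rRNA for 115 libraries, as raw counts with no normalisation. A second table, pooled by the authors, gives RPM for 13 tissues or cells: the counts of all libraries of a tissue were summed and divided by their total, rRNA left out and gene rows included, so its columns have no replicates, and its 23845 gene rows are found there only. The genome build named is mm10, and the aligner and its version are not given in the sources used here. Both units were checked on the values.

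The libraries fell into 30 groups of 14 tissues and cells, by tissue and diet as the labels give them: cauda sperm (8 per diet), caput sperm (4), caput epididymis (6), cauda epididymis (5), cauda epididymosomes (6), testis (9), liver, muscle and blood (2 each per diet), spermatocytes, SPTA and SPTB spermatids (4 each) and ES cells named GFP, LNA and tRF (2 each), HiO2 and LoO2 (1 each). The authors' table numbers the spermatids, and the first and the second kind were taken as SPTA and SPTB by that order alone. Control testis library number 6 carries a question mark in its name and was kept as testis. The rank correlation of its piRNA profile with the mean of the other testis libraries was 0.972, against 0.990 or more for the others. The tRF columns are named tRF-GG in full. What LNA, tRF-GG, HiO2 and LoO2 stand for was taken no further than the names. Spermatocytes, spermatids and the GFP, LNA and tRF libraries carry no diet label and were tested. Other libraries with no diet given, the high fat library and the fusion libraries entered no test. Total counts ran from 127664 to 18866566 per library. Read counts are not independent molecules, so any interval would cover counting error only. In 251 pairs of libraries of the same group the lowest chi-square per degree of freedom was 52.9, so no pair repeated another library.

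The 3723 rows were summed to 2754 features (53 tRNA anticodons, 1046 miRNAs, 1123 miRNA loci, 214 piRNA clusters, 313 repeats and 5 rRNA), and rRNA was left out of the tests. This summing replaced a rule that took the row with the highest mean of each anticodon or miRNA. Features with a mean of at least 10 CPM over the libraries of a comparison were tested with edgeR 4.0.16 (TMM, robust quasi-likelihood F-test, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the features tested and a threshold of 0.05. The SE was derived from the log2 fold change and F. Tissue comparisons carried both diets with the diet as a term. tRNA shares were compared with two-sided permutation tests (100000 resamples, exact with fewer than 10 libraries in a group; scipy 1.17.1), adjusted over 14 tests. Differences of diet effects between tissues were tested as interaction terms.

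The lists were fixed before the data were examined, as were the comparisons, tests and most alternatives. They are glycine, glutamate, valine, histidine, lysine, aspartate, mitochondrial (0 members in the table) and other nuclear tRNAs; the let-7, miR-34 and miR-449, miR-200, miR-10 to miR-125, miR-29, miR-30 and miR-181 families; the miR-17 to miR-92 and miR-182, miR-183, miR-96 clusters; the X-linked testis and Dlk1-Dio3 clusters; and markers of smooth muscle, striated muscle, liver, erythroid, white blood and pluripotent cells. Each list of at least 3 tested members was tested with camera (limma 3.58.1), with a preset correlation of 0.01 and with an estimated one, and with fry. Named features are a fixed panel of 10 tRNA anticodons and 12 miRNAs; the 5 largest rises and 5 largest falls among features past the threshold in the upper 25% of abundance; every passing feature where fewer than 6 passed; the 2 of lowest unadjusted p where none passed; and the most abundant tested member of each list. Panel members not printed are counted in their list. Single transcripts named from the pooled table were chosen after their values were seen.

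The alternatives were DESeq2 1.42.0, scaling to the miRNA sum, no filter, a minimum mean of 100 CPM, control diet alone, leaving out pools, and leaving out each library in turn where a group held 2 to 5. Chosen after seeing the data were library size alone, rRNA kept, rows not summed, leaving out the 4 cauda sperm libraries in which piRNA clusters were the largest class, leaving out the epididymosome libraries noted 6 weeks, and the code in the column names as a replicate block, within which diet differences, and tRNA shares where at least 6 pairs shared a code, were tested by exact sign flips over codes. For the shares the pairs were first flipped as independent (exact sign-flip p = 0.00195 for cauda and caput epididymis, 0.0313 for cauda sperm and testis); since both diets of a code are linked, this was replaced by flips over codes. The names of the 4 piRNA-rich libraries carry no such code, and they were paired across diets, and with testis, by the number of mice in the name, which does not show that they were handled together. No paired analysis was possible by title number because the columns carry no title numbers. Other splits of the samples into groups of the same sizes were counted, at most 100 per comparison. The tests were tried on simulated data with changes of 2-fold and 4-fold: edgeR recovered 70 and 96 of 100 in the comparison of cauda sperm and testis, and 0 and 0 of 100 in the diet comparison of caput sperm.

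The test of scaling by the tRNA counts was first made on the X-linked cluster, which that scaling can only lower further, and was then replaced by the let-7 and miR-200 families. For 1 test, of the whole caput epididymis as the source of let-7 in caput sperm, the criterion was changed more than once after the result was known. First, caput sperm had to lie above caput epididymis with an exact permutation p under 0.05, which it does. Then its mean had to exceed every caput epididymis library, which it does not. In the form used here it also had to lie above in the libraries that share a code, which it does not, so that source is left open. Gene lists for the pooled table (epididymal epithelium, spermatids, hemoglobin, Sertoli and Leydig cells, seminal vesicle, histones, ribosomal proteins, snoRNA and spliceosomal RNA) were summed per column. Figures were drawn with matplotlib 3.10.9, and tables handled with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.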

Results

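The libraries follow small RNAs through male germ cells, testis, the epididymis (the duct in which sperm mature while they pass from its caput to its cauda), the sperm taken from both ends of that duct, and epididymosomes, the vesicles shed into the lumen of the epididymis. Liver, muscle, blood and embryonic stem (ES) cells were sequenced beside them. Most tissues came from males on a control or a low protein diet. Total counts per library ran from 127664 to 18866566 over 115 libraries. Changes are given as log2 fold changes ± SE, levels as mean ± SD in CPM (counts scaled to library size by TMM) or, for pooled values, RPM. The edgeR p-values set a difference against the spread between these libraries, which the main fits took as independent although some share a name code. Groups were scaled by TMM, so a change is relative to the bulk of the features tested. Camera tests whether a list moved against the other features, with a preset correlation of 0.01. In the tissue comparisons, counts adjusted over the list alone equalled those over all features unless both are given.

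tRNA-derived reads made up most of the annotated small RNA in sperm and little of it in testis. Of the tRNA and miRNA counts together, tRNA took 83.1% ± 19.1 (SD, n = 16) in cauda sperm, 68.6% ± 20.8 (SD, n = 8) in caput sperm and 21.5% ± 8.20 (SD, n = 18) in testis. In cauda epididymosomes the share was 87.8% ± 6.56 (SD, n = 12), against 65.7% ± 14.7 (SD, n = 10) in cauda epididymis and 46.8% ± 21.7 (SD, n = 12) in caput epididymis. Spermatocytes held 26.8% ± 7.12, SPTA spermatids 33.6% ± 5.12 and SPTB spermatids 43.3% ± 15.03 (SD, n = 4 each). Liver, muscle and blood held 36.9% ± 3.19, 35.9% ± 10.6 and 19.6% ± 11.3 (SD, n = 4 each). The share was higher in cauda sperm than in testis (adjusted p = 7e-05, two-sided permutation test, the smallest it can give for this family), in caput sperm than in testis (adjusted p = 3.6e-05, exact permutation test) and in epididymosomes than in cauda epididymis (adjusted p = 9.3e-05, permutation test). The difference between cauda and caput sperm was within the spread between libraries (adjusted p = 0.286, exact permutation test), as was that between epididymosomes and cauda sperm (adjusted p = 0.645, permutation test). Cauda epididymis was not told apart from caput epididymis over all libraries (adjusted p = 0.107, permutation test), but lay above it without the 2 pools, caput libraries with 0.911 and 2.33% rRNA (22.8 points, adjusted p = 0.0475, permutation test). It was higher in 10 of 10 pairs that share a code and a diet, by 22.8 points, but these come from 5 codes (exact sign-flip p over codes = 0.0625, the smallest possible; chosen after seeing the data). With all counts, rRNA included, as the denominator, that difference was 2.67 points (2.43 between cauda and caput sperm, 59.0 between epididymosomes and cauda epididymis). Without the 4 cauda sperm libraries in which piRNA clusters were the largest class, the share in cauda sperm lay 23.4 points above that in caput sperm (adjusted p = 0.000611, exact permutation test). Those 4 were picked after seeing the data and hold the 4 lowest shares in cauda sperm, 27.7 to 78.3% against 83.4% or more. Leaving them out therefore raises the difference, and this p-value decides nothing.

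**Figure D1:**
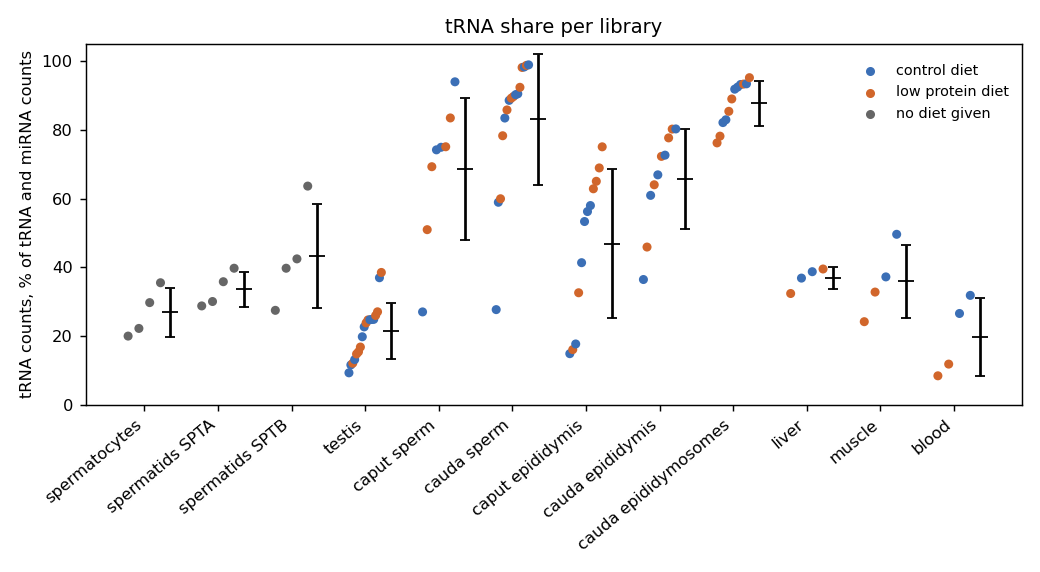
Each point is 1 library, coloured by diet, and shows the tRNA counts as a percentage of its tRNA and miRNA counts; bars beside the points give mean and SD. Cauda sperm and epididymosomes have means of 83.1% and 87.8%, testis 21.5%, and a few cauda sperm libraries lie far below the others.

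Cauda sperm and testis differed across the tRNA set and in many miRNAs. All 46 tRNA features tested were higher in cauda sperm (n = 16) than in testis (n = 18), with a median log2 change of 5.75, and they stayed higher under every scaling tried. tRNA-Glu-CTC rose by 7.43 ± 0.70, tRNA-Val-CAC by 7.36 ± 0.75, tRNA-Lys-CTT by 6.76 ± 0.63 and tRNA-Gly-GCC by 6.17 ± 0.55, the last from 665 ± 764 to 47773 ± 54696 normalised CPM. The largest rises among abundant features were tRNA-SeC(e)-TCA at 8.63 ± 0.69, tRNA-Trp-CCA at 8.35 ± 0.77, tRNA-Arg-CCG at 7.82 ± 0.75 and tRNA-Arg-TCG at 7.63 ± 0.68. By list, 3 of 3 glycine, 3 of 3 valine, 2 of 2 glutamate and 2 of 2 lysine tRNAs rose, as did histidine tRNA-His-GTG (5.87) and aspartate tRNA-Asp-GTC (3.64). The other nuclear tRNAs rose in 34 of 34 (camera adjusted p = 1.5e-13; adjusted p = 0.551 with an estimated correlation), and the glycine tRNAs had a camera adjusted p of 0.0406 (adjusted p = 0.551 with an estimated correlation).

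Among miRNAs, 108 rose and 40 fell of 214 tested in cauda sperm against testis, and 65 rose and 73 fell under the miRNA sum. All 5 members of the miR-200 family, epithelial miRNAs that repress Zeb1 and Zeb2, rose, with Mir200b at 3.70 ± 0.33 (camera adjusted p = 0.012; adjusted p = 0.551 with an estimated correlation). Of the let-7 family, which represses growth genes in differentiated cells, 8 of 9 rose, with Mirlet7a at 1.76 ± 0.29 and Mirlet7f at 1.01, and the list itself had a camera adjusted p of 0.0676. Mir451a, a miRNA of red blood cells, rose by 5.13 ± 0.75, and Mir223, a miRNA of myeloid cells, by 1.97. All 3 erythroid and 4 of 4 white blood cell markers tested rose. Mir451a and Mir451b had nearly the same level in cauda sperm (4318 and 4314 normalised CPM), as had Mir486 and Mir3107; how reads shared by such pairs were counted is not given, so they are not separate evidence. Mir182 rose by 3.43 ± 0.30, Mir10a by 3.09 ± 0.45 and Mir369 by 2.97 ± 0.29. In the miR-34 and miR-449 family, which is abundant in male germ cells, 3 of 5 fell, while Mir34b changed by -0.01 ± 0.23 and Mir34c by 0.73 ± 0.39 (adjusted p = 0.0776). The X-linked testis cluster gave 6 rises and 3 falls of 18 (4 and 2 adjusted over the list alone). Scaled to the miRNA sum it gave no rise and 8 falls, and by library size no rise and 6 falls. Of the piRNA clusters, the genomic sources of small RNAs that silence transposons in germ cells, 134 of 210 fell and 52 rose. The deepest falls were pi-10-qB5.1-5404 at -2.22 ± 0.39, pi-9-qA5.3-1495 at -2.19, pi-1-qD-4525 at -2.17, pi-15-qE1-3710 at -2.16 and pi-2-qF1-2536 at -2.12. The 4 piRNA-rich cauda sperm libraries held 51.6 to 92.9% piRNA counts without rRNA, and without them 143 piRNA clusters fell and 40 rose. In all, 396 of 489 features changed, 214 up and 182 down. Scaled to the miRNA sum, 143 rose and 229 fell, and by library size 143 and 196, with shifts of the median of all features of -0.52 and -0.41 (0.14 by DESeq2). With the library code as a block, which left 12 libraries, 109 changed; 4 of its 6 pairs hold the piRNA-rich libraries, matched to testis by the number of mice in the name alone.

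Caput sperm (n = 8) also carried more of every tRNA tested than testis (n = 18), and far less of the testis miRNAs. The caput sperm and testis libraries share no name code, so a difference between codes cannot be told from a difference between tissues. All 46 tRNA features rose, with a median of 5.36: tRNA-Trp-CCA by 7.69, tRNA-Ala-AGC by 7.54, tRNA-Lys-CTT by 6.92 ± 0.50, tRNA-Glu-CTC by 6.39 ± 0.42 and tRNA-Gly-GCC by 5.93 ± 0.50. All 18 tested members of the X-linked testis cluster, a run of miRNA genes expressed in testis, fell under every scaling (camera adjusted p = 0.000547; adjusted p = 0.477 with an estimated correlation), with Mir881 at -6.16 ± 0.55, Mir871 at -4.73 ± 0.42 and Mir465 at -4.63 ± 0.37. In the miR-34 and miR-449 family 5 of 5 fell, Mir34b by -5.63 ± 0.41, from 5058 ± 2185 to 102 ± 61.8 normalised CPM, and Mir34c by -3.19 ± 0.64. Mir202, a gonadal miRNA, fell by 9.59 ± 0.51 on the log2 scale. Of the piRNA clusters 141 of 210 fell and 44 rose, with pi-17-qC-935 at -6.65 ± 0.32, pi-8-qC5-8200 at -6.62 ± 0.39, pi-18-qE1-36451 at -6.60 ± 0.31 and pi-9-qC-31469 at -6.60 ± 0.35.

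In the opposite direction, all 9 let-7 members rose in caput sperm (camera adjusted p = 0.00154; adjusted p = 0.477 with an estimated correlation), with Mirlet7b at 4.75 ± 0.22, Mirlet7c at 4.60 ± 0.23 and Mirlet7a at 2.70. All 5 members of the miR-200 family rose (camera adjusted p = 0.00415; adjusted p = 0.477 with an estimated correlation), led by Mir200c at 7.95 ± 0.53, from 34.4 ± 37.1 to 8549 ± 4992 normalised CPM. The cluster of miR-182, miR-183 and miR-96 rose in 3 of 3 (adjusted p = 0.0307; adjusted p = 0.245 with an estimated correlation), and Mir10a, a miRNA of the Hox clusters, rose by 6.00 ± 0.62. All 6 pluripotent cell markers passed, but Mir295 at 6.64 ± 0.94 rested on a few libraries (440.4 ± 874 against 4.06 ± 3.61 normalised CPM). In the authors' pooled table, transcripts of epididymal epithelium summed to 2973 RPM in caput sperm, 3089 in caput epididymis and 11.69 in testis, with no replicates. In all, 425 of 500 features changed, 196 up and 229 down. Scaled to the miRNA sum 97 rose and 331 fell, with a shift of the median of -1.88 (0.53 by DESeq2 and 0.22 by library size), and Mir125b, Mir181a and Mir30c turned direction.

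Cauda and caput sperm differed in the let-7 and testis miRNAs, and how many let-7 members differed depended on the scaling. The libraries of cauda and caput sperm share no name code either, so here too code and tissue cannot be told apart. All 9 let-7 members were lower in cauda sperm (n = 16) than in caput sperm (n = 8), with camera adjusted p = 1.1e-06 (adjusted p = 0.232 with an estimated correlation) and 9 of 9 adjusted over the list alone. Mirlet7c fell by 5.27 ± 0.38 on the log2 scale, from 114328 ± 44360.4 to 2996 ± 1820.0 normalised CPM, Mirlet7b by 5.03 ± 0.32, Mirlet7e by 4.31 ± 0.31 and Mirlet7f by 2.96 ± 0.39. Scaled to the miRNA sum, only 3 of the 9 fell and Mirlet7a changed by 0.53. That sum is mostly let-7 itself in the caput sperm libraries tested, so scaling to it can hide part of a fall. As a share of the miRNA counts, the family as a whole took 53.6 to 83.5% in the caput sperm libraries and 3.35 to 34.3% in the cauda sperm libraries. Caput sperm libraries that entered no test held 11.1, 25.1 and 67.3%. The miR-200 family fell in 5 of 5 (camera adjusted p = 0.00244; adjusted p = 0.257 with an estimated correlation), with Mir200c at -4.91 ± 0.46 and Mir200b at -2.95 ± 0.40, and only 1 fell under the miRNA sum. The family of miR-10, miR-99, miR-100 and miR-125 fell in 6 of 7 (adjusted p = 0.00193; adjusted p = 0.232 with an estimated correlation), with Mir10a at -3.99 ± 0.66 and Mir10b at -3.50 ± 0.48; under the miRNA sum 1 rose and 3 fell. The miR-181 family fell in 4 of 4 (adjusted p = 0.00913; adjusted p = 0.232 with an estimated correlation), but gave 1 rise and 1 fall under the miRNA sum. The cluster of miR-182 fell in 3 of 3 (adjusted p = 0.0258; adjusted p = 0.232 with an estimated correlation) and the pluripotent markers in 6 of 6 (adjusted p = 0.0605). The miR-29 family fell in 3 of 3 (adjusted p = 0.114), with none past the threshold and a median of 0.48 under the miRNA sum. Mir204 had the largest fall, -6.27 ± 0.63. In the authors' pooled table, with no replicates, epididymal epithelium transcripts summed to 2973 RPM in caput sperm and 364.3 in cauda sperm. Spermatid transcripts summed to 6.61 and 69.1. Those columns also sum libraries that entered no test.

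On the other side, all 18 tested members of the X-linked testis cluster rose in cauda sperm, under every scaling but 16 of 18 with control diet alone and without the 4 piRNA-rich libraries (camera adjusted p = 1.4e-15; adjusted p = 0.0744 with an estimated correlation). Mir465 rose by 4.61 ± 0.56, Mir465c by 4.59 ± 0.62 and Mir871 by 4.34 ± 0.56. In the miR-34 and miR-449 family 3 of 4 rose (adjusted p = 0.0167; adjusted p = 0.232 with an estimated correlation), with Mir34b at 4.80 ± 0.45 and Mir34c at 3.26 ± 0.65. The miR-17 to miR-92 clusters rose in 6 of 9 (adjusted p = 0.153), striated muscle markers in 4 of 4 (adjusted p = 0.0983), erythroid markers in 3 of 3 (adjusted p = 0.355) and white blood cell markers in 2 of 4, none of which passed when adjusted over the list alone. Mir202 rose by 6.91 ± 1.41 and pi-18-qE1-36451 by 4.68 ± 1.09, and by 3.65 and 2.58 without the 4 piRNA-rich libraries. Of 49 tRNA features, 2 rose and 9 fell; scaled to the miRNA sum 19 rose and none fell. tRNA-Val-CAC changed by 1.95 ± 0.92 (adjusted p = 0.065), and by 2.57 (adjusted p = 0.0055) without those 4 libraries, while tRNA-Gly-GCC changed by -0.89 ± 0.69 and tRNA-Glu-CTC by -0.11 ± 0.74. In all, 333 of 506 features changed, 159 up and 174 down. Scaled to the miRNA sum 354 rose and 30 fell, with a shift of the median of 2.29, and by library size 149 rose and 94 fell, with one of 0.25.

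**Figure D2:**
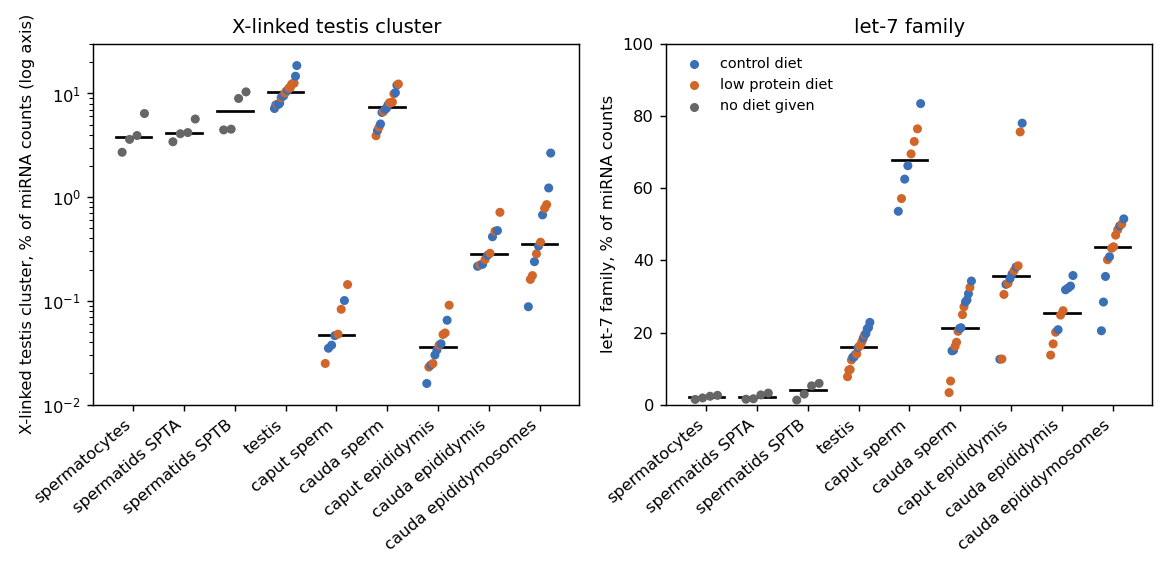
Each point is 1 library, coloured by diet, and shows the X-linked testis cluster (left, log axis) and the let-7 family (right) as a percentage of its miRNA counts; horizontal lines are medians. Caput sperm lies with caput epididymis on the left, and cauda sperm with testis; both percentages are within miRNA counts, so scaling of the tRNAs has no part in them.

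**Figure D3:**
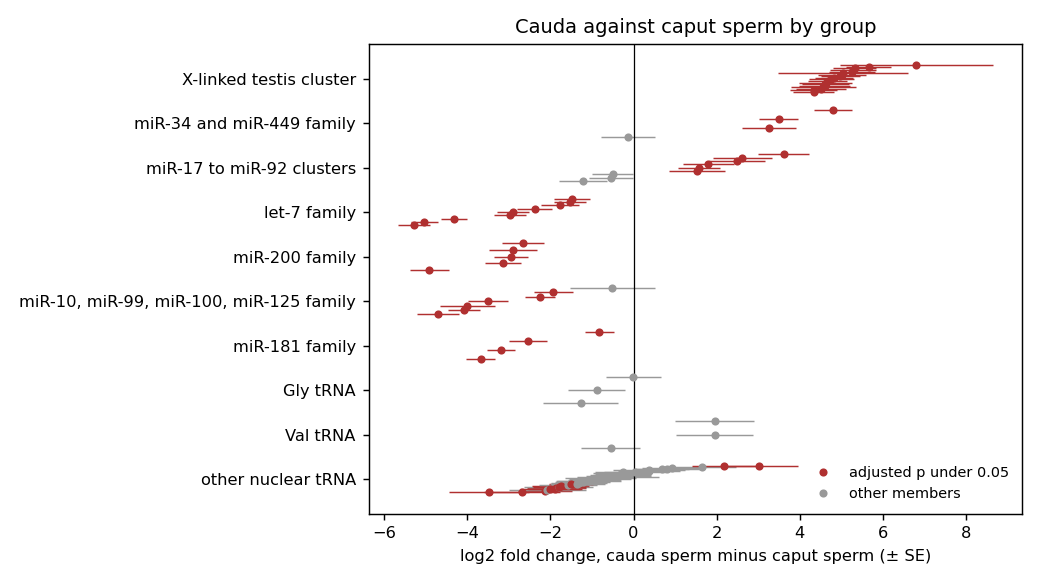
Points are members of each list with their log2 fold change of cauda over caput sperm and bars are SE; red marks adjusted p under 0.05. The let-7, miR-200 and miR-10 lists lie below 0 and the X-linked list above it, but scaled to the miRNA sum only 3 of 9 let-7 members fell and the tRNA lists had medians above 0. In caput sperm that sum is mostly let-7 itself.

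Cauda epididymis (n = 10) and caput epididymis (n = 12) differed as well. All 15 tested members of the X-linked testis cluster were higher in cauda than in caput epididymis (camera adjusted p = 1.4e-21; adjusted p = 0.000834 with an estimated correlation, so the call held), with Mir871 at 3.41 ± 0.35 and Mir465 at 2.78 ± 0.36. Spermatid transcripts were higher in cauda epididymis too, at 7.71 against 2.65 RPM in the pooled table, which has no replicates. The rank correlation of the piRNA profile with testis was 0.25 to 0.889 against at most 0.207. The piRNA share of the counts without rRNA went the other way, 4.78% ± 3.28 (SD, n = 10) against 8.39% ± 5.46 (SD, n = 12). Mir196b, which sits in a Hox cluster, had the largest rise, 5.93 ± 0.40, from 67.8 ± 36.8 to 4194 ± 1714 normalised CPM, and Mir196a rose by 2.94 ± 0.35. The smooth muscle miRNAs Mir145a and Mir143 rose by 2.70 ± 0.57 and 2.26 ± 0.44, and 3 of 3 striated muscle markers rose (adjusted p = 0.0908; none under library size scaling). The valine tRNAs rose in 3 of 3 (adjusted p = 0.0396; adjusted p = 0.608 with an estimated correlation), with tRNA-Val-AAC at 2.49 ± 0.43 and tRNA-Val-CAC at 2.44 ± 0.43. Among glycine tRNAs, tRNA-Gly-TCC rose by 1.72 ± 0.48 and tRNA-Gly-CCC by 1.71 ± 0.62 while tRNA-Gly-GCC changed by -0.07 ± 0.49. The Dlk1-Dio3 cluster, imprinted miRNA genes, rose in 8 of 15 (adjusted p = 0.0298; adjusted p = 0.787 with an estimated correlation) but in none under library size scaling, and other nuclear tRNAs in 8 of 37, 4 adjusted over the list alone (adjusted p = 0.0465; adjusted p = 0.810 with an estimated correlation). White blood cell markers rose in 4 of 5 (adjusted p = 0.177). Falls included Mir204 at -4.08 ± 0.59, Mir135a at -2.70 ± 0.55, Mir20a at -2.53 ± 0.48, Mirlet7b at -2.07 ± 0.64 and Mirlet7c at -1.40 ± 0.54; 4 of 9 let-7 members fell (3 adjusted over the list alone; adjusted p = 0.337), 3 of 5 of the miR-200 family and 3 of 3 of the miR-182 cluster (adjusted p = 0.129). The caput epididymis pools held 78.0 and 75.6% let-7 among their miRNA counts. The other caput epididymis libraries held 12.6 to 38.5% and cauda epididymis 13.8 to 35.8%, so the let-7 falls may rest on the pools. In all, 275 of 551 features changed, 119 up and 156 down. By library size 69 rose and 208 fell, with a shift of the median of -0.54 (0.12 by DESeq2), under the miRNA sum 113 rose and 96 fell, and with control diet alone 79 changed, 62 up and 17 down.

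Cauda epididymosomes (n = 12) carried more tRNA-derived reads than the cauda epididymis (n = 10). Of 49 tRNA features 40 rose and 1 fell, with tRNA-Arg-CCG at 3.86 ± 0.52, tRNA-SeC(e)-TCA at 3.85 ± 0.52, tRNA-Cys-GCA at 3.78 ± 0.63 and tRNA-Trp-CCA at 3.45 ± 0.53. The valine tRNAs rose in 3 of 3 (camera adjusted p = 0.00882; adjusted p = 0.514 with an estimated correlation), the glycine tRNAs in 3 of 3 (adjusted p = 0.152), glutamate tRNAs in 2 of 2 (none by library size), lysine tRNAs in 2 of 2 and the other nuclear tRNAs in 30 of 37 with 1 fall (adjusted p = 2.2e-08; adjusted p = 0.514 with an estimated correlation). tRNA-Glu-CTC and tRNA-Gly-GCC each rose by 2.23 ± 0.40, and tRNA-Lys-CTT by 2.87 ± 0.51. Scaled by library size, 14 tRNAs rose and 6 fell, and the glycine tRNAs had a median of -0.27. The Dlk1-Dio3 cluster rose in 12 of 16 (adjusted p = 8.8e-05; adjusted p = 0.514 with an estimated correlation; by library size 3 rose and 3 fell), as did Mir369 at 2.47 ± 0.44. Let-7 members rose in 4 of 9 (adjusted p = 0.150), with Mirlet7b at 1.72 ± 0.39; by library size 2 fell and none rose. The X-linked cluster rose in 6 of 16, 5 adjusted over the list alone (adjusted p = 0.152), and fell in 8 by library size. Falls included Mir141 of the miR-200 family at -2.47 ± 0.39, Mir135a at -2.13 ± 0.34, Mir29b at -2.03 ± 0.34, Mir126a, a miRNA of endothelial cells, at -2.02 ± 0.29. Mir143 fell by 1.88 ± 0.37 on the log2 scale. Of 200 piRNA clusters 135 fell and 1 rose, with pi-Phf20 at -2.78 ± 0.28. In all, 325 of 498 features changed, 132 up and 193 down. By library size 23 rose and 342 fell, with a shift of the median of -1.48, by DESeq2 163 rose and 149 fell, with one of 0.30, and with control diet alone 175 changed.

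Set against cauda sperm (n = 16), the epididymosomes (n = 12) carried much more of the let-7, Dlk1-Dio3 and smooth muscle miRNAs and less of the testis miRNAs. All 12 tested Dlk1-Dio3 members rose (camera adjusted p = 5.6e-09; adjusted p = 0.0151 with an estimated correlation, so the call held). All 9 let-7 members rose (adjusted p = 0.000602; adjusted p = 0.360 with an estimated correlation), with Mirlet7c at 3.67 ± 0.38 and Mirlet7b at 3.38, and 4 of 9 under the miRNA sum, where Mirlet7a turned to -0.35. The miR-10, miR-99, miR-100 and miR-125 family rose in 6 of 7 (adjusted p = 0.000383; adjusted p = 0.0619 with an estimated correlation), with Mir99a at 3.91 ± 0.38 and Mir125b at 3.70 ± 0.32, and the miR-181 family in 4 of 4 (adjusted p = 0.00229; adjusted p = 0.200 with an estimated correlation). The miR-200 family rose in 5 of 5 (adjusted p = 0.0358; adjusted p = 0.614 with an estimated correlation) but in none under the miRNA sum. Mir199b rose by 5.07 ± 0.41, Mir199a by 5.05 ± 0.40, Mir196b by 4.35 ± 0.39, Mir145a by 3.98 ± 0.66 and Mir143 by 3.86 ± 0.48. The X-linked cluster fell in 17 of 17 (adjusted p = 0.0174; adjusted p = 0.729 with an estimated correlation), with Mir465 at -2.79 and Mir871 at -2.67, the miR-34 and miR-449 family in 3 of 4 (adjusted p = 0.400), with Mir34c at -2.86 ± 0.50 and Mir34b at -2.72 ± 0.37, and the erythroid markers in 3 of 3. Of 208 piRNA clusters 193 fell and 1 rose, with pi-18-qE1-36451 at -4.85 ± 0.86 and pi-8-qE1-3748 at -4.44 ± 0.45. The value of pi-Igf2bp1, -4.40 ± 1.61, rested on 1 cauda sperm library and changed by 0.67 without the 4 piRNA-rich libraries. The most abundant tRNAs differed little: tRNA-Glu-CTC by -0.01 ± 0.69, tRNA-Val-CAC by 0.06 ± 0.66 and tRNA-Gly-GCC by 0.72 ± 0.60, none past the threshold. Of 48 tRNAs 18 rose and none fell, and under the miRNA sum 1 rose and 9 fell. Among the other nuclear tRNAs 14 of 36 rose, 11 adjusted over the list alone, and 1 rose and 5 fell under the miRNA sum (adjusted p = 0.00354; adjusted p = 0.729 with an estimated correlation). In all, 414 of 500 features changed, 143 up and 271 down. By DESeq2 201 rose and 188 fell, with a shift of the median of 1.13, and under the miRNA sum 71 rose and 318 fell, with one of -1.6 (-0.88 by library size).

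Within the germ line, piRNA clusters dominated, and no single feature passed between stages. By their names the 3 stages come from the same 4 mice; the tests took them as unpaired, and with the mouse as a block the counts were 0 and 0 as well. The authors' table names the spermatids by number, and they were taken as SPTA and SPTB in that order; the other order would exchange their values and turn the sign of every difference between them. Of the counts without rRNA, piRNA clusters took 95.5% in spermatocytes, 95.8% in SPTA spermatids and 95.01% in SPTB spermatids (n = 4 each). Between SPTA spermatids and spermatocytes none of 384 features passed by edgeR, with 4 at an unadjusted p under 0.05 and 0 by DESeq2. The lowest p values were those of Mir122a, a liver miRNA, at -6.61 ± 2.55 and Mir350 at 0.43 ± 0.18 (adjusted p = 0.748 for both). Between SPTB and SPTA spermatids none of 382 passed by edgeR, with 42 at an unadjusted p under 0.05 and 8 by DESeq2. Mir100 differed by 1.04 ± 0.20 and Mir26a by 0.90 ± 0.18 (adjusted p = 0.137 for both), and 3 of 3 members of the miR-10, miR-99, miR-100 and miR-125 family passed when adjusted over the list alone (camera adjusted p = 0.000593; adjusted p = 0.249 with an estimated correlation). The X-linked testis cluster had a camera adjusted p of 0.0112 upward in SPTB (adjusted p = 0.463 with an estimated correlation), with Mir881 at 1.80 ± 0.71 not passing alone. Between SPTA spermatids and spermatocytes the miR-30 family moved down and the other nuclear tRNAs up by camera (adjusted p = 0.046 for both; adjusted p = 0.537 for both with an estimated correlation).

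In cauda sperm the low protein diet went with more glycine tRNA reads and fewer let-7 reads, as lists rather than as single features (n = 8 per diet). The glycine tRNAs moved up by camera (adjusted p = 0.000141, and 0.139 with an estimated correlation of 0.804). The let-7 family moved down by camera (adjusted p = 8.1e-09, and 0.139 with an estimated correlation of 0.649). By fry neither list passed (adjusted p = 0.520 for both). Across the 8 library codes that pair the diets, the mean of the glycine tRNAs was higher on low protein in 8 of 8, by 1.62 ± 0.55 on the log2 scale (SD, n = 8; exact sign-flip p = 0.00781, the smallest possible; adjusted p = 0.0188 over 12 measures in this tissue and 0.0938 over 72 in all). tRNA-Gly-CCC was higher in 8 of 8 by 1.80, tRNA-Gly-TCC in 8 of 8 by 2.10 and tRNA-Gly-GCC in 7 of 8 by 0.97. The mean of the other tRNAs was higher in 4 of 8, by 0.17. The 4 piRNA-rich libraries carry no code and were paired by the number of mice in the name; without them the glycine tRNAs were higher in 6 of 6, by 1.48 (exact sign-flip p = 0.0313), and let-7 lower in 5 of 6, by -0.84 (exact sign-flip p = 0.0625). The let-7 mean was lower in 7 of 8 codes, by -0.69 ± 0.64 (SD, n = 8; exact sign-flip p = 0.0234, adjusted p = 0.0313 over the 12 measures and 0.105 over all 72), with Mirlet7a lower in 8 of 8. With the code as a block, camera gave the glycine tRNAs an adjusted p of 4.6e-08 (adjusted p = 0.0104 with an estimated correlation, so the call held) and let-7 3.6e-07 (adjusted p = 0.2 with an estimated correlation). The miR-17 to miR-92 clusters moved up by camera (adjusted p = 0.0355; adjusted p = 0.762 with an estimated correlation). No single feature passed by edgeR; 11 lay at an unadjusted p under 0.05 and DESeq2 gave 0. tRNA-Gly-TCC changed by 1.89 ± 0.82 and Mirlet7a by -1.03 ± 0.48, both at an adjusted p of 0.952, and with the block tRNA-Gly-TCC changed by 2.12 (adjusted p = 0.0726).

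**Figure D4:**
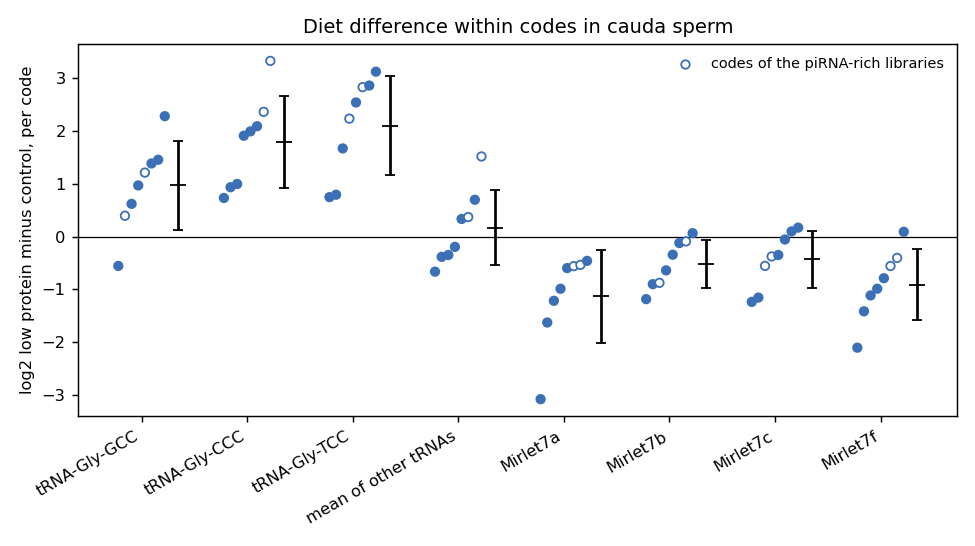
Each point is 1 library code in cauda sperm and shows the log2 difference of low protein minus control; bars beside the points are mean and SD, and open circles are codes with a piRNA-rich library. All 8 points of tRNA-Gly-CCC and tRNA-Gly-TCC lie above 0 and all 8 of Mirlet7a below it.

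In the other tissues the diet moved few single features. In testis (n = 9 per diet) none passed by edgeR, with 87 at an unadjusted p under 0.05 and 21 by DESeq2. The let-7 family moved down by camera (adjusted p = 2.5e-07; adjusted p = 0.382 with an estimated correlation), with 9 of 9 passing adjusted over the list alone. Mir742 differed by 1.40 ± 0.31 and tRNA-Leu-CAG by 1.59 ± 0.36, both at an adjusted p of 0.0632. In cauda epididymis (n = 5 per diet) none passed by edgeR, with 57 unadjusted and 7 by DESeq2. let-7 moved down by camera there (adjusted p = 6.3e-06; adjusted p = 0.612 with an estimated correlation), and Mir143 differed by 1.31 ± 0.34 (adjusted p = 0.191). In caput sperm (n = 4 per diet) none passed by edgeR, with 7 unadjusted and 0 by DESeq2. The other nuclear tRNAs moved down by camera (adjusted p = 2.5e-07; adjusted p = 0.610 with an estimated correlation) and Mir148b differed by -3.08. In caput epididymis (n = 6 per diet) none passed by edgeR, with 6 unadjusted and 0 by DESeq2, and the miR-30 family moved down by camera (adjusted p = 7e-05; adjusted p = 0.357 with an estimated correlation). In epididymosomes (n = 6 per diet) none passed by edgeR, with 11 unadjusted and 0 by DESeq2, and white blood cell markers moved up by camera (adjusted p = 0.000638; adjusted p = 0.198 with an estimated correlation), 2 of them adjusted over the list alone. In liver (n = 2 per diet) 7 features passed, 1 up and 6 down: Mir122a (locus) at -4.62 ± 0.82, IAPEY5_I:ERV2 at -3.26 ± 0.73, Mir3071 at -3.08, Mir136 at -2.90, IAP1-MM_I:ERV2 at -2.76, Mir148b at -2.62 and Mir3473c at 3.87 ± 0.94. The mature Mir122a differed by -0.35 ± 0.80. With 2 libraries per diet, leaving 1 out leaves a single library in a diet, so the stability of the 7 calls could not be checked that way. In muscle none passed by edgeR, with 20 unadjusted and 4 by DESeq2. Leaving 1 library out decides nothing in muscle either. There let-7 moved up by camera (adjusted p = 0.00233; adjusted p = 0.495 with an estimated correlation), as did the liver markers (adjusted p = 0.01; adjusted p = 0.454 with an estimated correlation). In blood none passed by edgeR, with 16 unadjusted and 16 by DESeq2. The valine tRNAs moved down by camera (adjusted p = 0.000773; adjusted p = 0.751 with an estimated correlation), 3 of 3 adjusted over the list alone, with tRNA-Val-CAC at -1.72 ± 0.52. The glycine tRNAs moved down too, against their direction in cauda sperm (median -1.55, adjusted p = 0.0185), as did the other nuclear tRNAs (adjusted p = 0.000257), the miR-30 family (adjusted p = 0.000773) and striated muscle markers (adjusted p = 0.0185), each at 0.751 with an estimated correlation. By camera, without the code as a block, 1 list passed in testis, 3 in cauda sperm, 6 in caput sperm, 3 in caput epididymis, 3 in cauda epididymis, 4 in epididymosomes, 2 in liver, 7 in muscle and 5 in blood. None of these fits gave a passing list with an estimated correlation. The diet effects in cauda sperm and in testis, caput sperm and cauda epididymis gave 2, 1 and 2 of 540 features in the test of their difference, but 0, 0 and 0 with the code as a block. These were pi-Igf2bp1 and pi-Mllt6 against testis and against cauda epididymis, which rest on 1 cauda sperm library, and tRNA-Leu-TAA against caput sperm. Without the 4 piRNA-rich libraries the count was 0 for testis and 0 for cauda epididymis, and 100, 79 and 72 of 100 splits of the libraries reached as many. For the glycine tRNAs the difference of effects against caput sperm had a camera adjusted p of 0.00286 (adjusted p = 0.357 with an estimated correlation), against testis 0.0556 and against cauda epididymis 0.187, so a difference between cauda sperm and the latter tissues was not shown.

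In ES cells the tRF libraries are named tRF-GG in full. Reads of any RNA given to the cells cannot be told from those the cells made. The tRF libraries held more tRNA-Gly-GCC reads than the GFP libraries (n = 2 each). The 2 tRF libraries held 50406 and 122762 RPM, the 2 GFP libraries 4833 and 7976, the 2 LNA libraries 4410 and 2915, the HiO2 library 5229 and the LoO2 library 4464. The fitted difference of tRF and GFP was 4.25 ± 0.76 (adjusted p = 0.288), and the glycine tRNAs moved up by camera (adjusted p = 2.8e-06; adjusted p = 0.733 with an estimated correlation), 2 of 3 adjusted over the list alone. The let-7 family moved down (adjusted p = 0.000657; adjusted p = 0.733 with an estimated correlation). None of the single features passed by edgeR, with 33 at an unadjusted p under 0.05 and 14 by DESeq2; Mir450 differed by -3.55 ± 0.55 (adjusted p = 0.246). Between LNA and GFP none passed by edgeR, with 27 unadjusted and 18 by DESeq2; tRNA-Gly-GCC differed by -0.77 ± 0.67 (adjusted p = 0.857) and Mir196b by -1.77 ± 0.38.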

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

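Of the tests in this part, those on RNA of testis cells and on the amount of tRNA as a whole were set before their results were seen; the others, and the leaving out of the 4 libraries, were chosen after.

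In the 8 caput sperm libraries tested, testis-type miRNAs and piRNA clusters were low while let-7 and miR-200 were high. In the authors' pooled table the epididymal epithelium transcripts summed to 2973 RPM in caput sperm, a signal in data that no comparison used, which is 0.962 of the 3089 in caput epididymis; Gpx5 stood at 1208 and 1419, and Adam7 at 553.1 and 586.7. RNA of caput epididymal cells in the caput sperm libraries may therefore account for part of the pattern, though the column also sums 3 libraries in no test, with 43.0% of its counts, which alone would need 6915 RPM, 2.24 times the level of caput epididymis, to give that sum. Scaling by the tRNA counts as the whole cause of the rises was argued against, since under the miRNA sum 6 of 9 let-7 and 5 of 5 miR-200 members stayed higher than in testis, with medians of 1.25 and 3.75 instead of 3.18 and 5.69; the low miRNAs and piRNA clusters only fall further under that scaling, which tests nothing. Whole caput epididymis as the source of the let-7 stays open: the let-7 share of the miRNA counts was 29.3 points higher in caput sperm (67.7% ± 9.97 SD, n = 8) than in caput epididymis (38.5% ± 20.03 SD, n = 12; exact permutation p = 0.00208, adjusted p = 0.00416 over 2 tests), but in the only code that both share it was lower, 66.3 against 78.0% on control and 57.1 against 75.6% on low protein diet, in the 2 caput epididymis libraries with 0.911 and 2.33% rRNA named below. The other of the 2 tests, on the X-linked share of the miRNA counts, gave 0.0649% ± 0.0409 (SD, n = 8) in caput sperm and 0.0401% ± 0.0210 (SD, n = 12) in caput epididymis. That difference did not pass (exact permutation p = 0.0869). Uptake or loss by the sperm was not tested. The caput sperm libraries tested share no name code with testis or cauda sperm, so differences between codes cannot be told from those between tissues.

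In 4 of the 16 cauda sperm libraries piRNA clusters were the largest class, with 51.6 to 92.9% of the counts without rRNA; their total counts (664914 to 1873350) lay below the 4053750 or more of the other 12, and 3 of them held 29.6 to 42.7% rRNA against at most 17.9%. Their piRNA profiles had a rank correlation with testis of at least 0.919, against 0.837 ± 0.0517 (SD, n = 12) in the other cauda sperm libraries, of which the highest was 0.938. RNA of testis cells in these libraries may account for them, though that highest value means that the profile does not set them apart. Loss of tRNA alone was argued against only weakly. In 4 of 4 the ratio of piRNA to miRNA counts lay above the highest of the others, 3.94, but the lowest of the 4 stood at 4.92. The 4 were picked for piRNA clusters as their largest class, which itself favours a high ratio. An exchange of labels with testis was argued against, since no testis library held over 4.49% tRNA while the lowest of the other cauda sperm libraries held 71.2%. A difference in yield or quality of the RNA and a difference between the males stay open and were not tested.

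Glycine tRNAs were higher and let-7 lower on the low protein diet in cauda sperm. The 4 piRNA-rich libraries as the cause were argued against, since both of the 2 lists passed camera without them (adjusted p = 3.7e-05 and 5.5e-08; adjusted p = 0.109 and 0.223 with an estimated correlation). A difference in tRNA as a whole was argued against, since within codes the glycine tRNAs moved by 1.46 more than the other tRNAs on the log2 scale, in 8 of 8 codes (exact sign-flip p = 0.00781). An effect of the diet on these RNAs is a hypothesis that both tests leave standing. But it was found and tested on the same libraries, and no single feature passed. Over all 72 exact sign-flip tests the adjusted p was 0.0938 for glycine and 0.105 for let-7. By fry over all 16 libraries neither list passed (adjusted p = 0.520 for both).

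A few libraries stood far from the rest of their group, by the gap to the nearest library as a share of the range: the rRNA percentage of caput epididymis control number 1 (0.871; 0.911% against 77.7 to 89.1%), low protein number 1 (0.808; 2.33% against 72.8 to 89.6%), SPTA number 2 (0.923) and spermatocytes number 2 (0.964), and the count without rRNA of caput epididymis low protein number 1 (0.684). These are 5 of 60 tests of a measure in a group, where chance gives 3, and 2 of the 5 are of the same library. The diet effect in cauda sperm differed from that in caput sperm in tRNA-Leu-TAA (3.39), from that in cauda epididymis in pi-Igf2bp1 (9.27) and pi-Mllt6 (4.0), and from that in testis in pi-Igf2bp1 (10.85) and pi-Mllt6 (4.30); the piRNA differences rest on 1 cauda sperm library. One of the 2 fusion epididymosome libraries held 34.1% piRNA, in a preparation that no comparison used. Spermatid transcripts, another signal that no comparison used, summed to 69.1 RPM in the authors' pooled cauda sperm column and 124.6 in testis; that column sums all cauda sperm libraries, so it says nothing about the 4 rich in piRNA.

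A random grouping of libraries was made unlikely for the 6 tissue comparisons, where 1 of 100 splits, the real one, reached the real count: cauda and caput sperm 333 (highest other 7), cauda sperm and testis 396 (66), caput sperm and testis 425 (138), cauda and caput epididymis 275 (137), epididymosomes and epididymis 325 (118), epididymosomes and cauda sperm 414 (270). That is the smallest share that 100 splits can show. The splits moved single libraries and did not keep libraries of the same code together. They cannot part tissue from code in the caput sperm comparisons. For the counts of 0 every split reaches the count by construction, so the splits decide nothing there and chance could not be excluded: SPTA and spermatocytes (35 of 35 splits; highest other 76), SPTB and SPTA (35 of 35; 1), and diet in cauda sperm (100 of 100; 1), caput sperm (35 of 35; 0), caput epididymis (100; 2), cauda epididymis (100; 92), epididymosomes (100; 4) and testis (100; 4). Among splits that part the paired libraries, the highest other was 0 in cauda sperm (8 pairs, 100 splits) and 0 in cauda epididymis (5 pairs, 16 splits). For the differences of diet effects, 100, 79 and 72 of 100 splits reached 2, 1 and 2 for testis, caput sperm and cauda epididymis, with highest others of 169, 155 and 136. Some splits call many more features than the real one (76 in the only other split of 35 with calls, 92 where 6 other splits of 100 had calls, and 169, 155 and 136 where 99, 78 and 92 had). They point to some structure of the samples, which was not tested further; single libraries such as the one behind the piRNA values enter the latter 3.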

How the results depend on the processing

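The tests with library size alone, rows not summed, the library code as a block, and without the 4 piRNA-rich or the 6-week libraries were chosen after seeing the data. Of 262 counts 194 stayed within 1.5 times the reported one and 68 moved. Of 1061 alternatives for 201 called features 892 kept direction and threshold, 147 kept direction only and 22 reversed. Of 473 list results 389 were the same, 77 weaker and 7 stronger. Results called the same include counts that stayed at 0, and lists and shares that passed in neither setting. In the diet comparisons without the code as a block, no list that passed camera also passed with an estimated correlation. Of 103 share results 100 were the same, 2 stronger and 1 weaker, though with all counts as the denominator the share of cauda epididymis lay only 2.67 points above caput epididymis, that of cauda sperm 2.43 above caput sperm, and that of epididymosomes 59.0 above cauda epididymis. Where no cause is named, the cause was not tested.

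At a mean of at least 100 CPM fewer features were tested and the counts were lower, though whether the one explains the other was not tested: cauda and caput sperm 201, cauda sperm and testis 247, caput sperm and testis 275, cauda and caput epididymis 161, epididymosomes and cauda epididymis 164, epididymosomes and cauda sperm 216, liver diet 0, and differences of diet effects 1 for testis and 1 for cauda epididymis. With rows as deposited more units were tested: 571, 823, 857, 524, 683 and 755 in the same 6 comparisons, diet in testis 7, liver 11 and muscle 15, tRF and GFP 16, and differences of diet effects 5 (testis), 0 (caput sperm) and 5 (cauda epididymis). With no filter, cauda sperm and testis gave 847, caput sperm and testis 806, epididymosomes and cauda sperm 690, diet in cauda epididymis 6, muscle 9 and blood 7, tRF 8, LNA 4, and differences of diet effects 0 (caput sperm) and 0 (cauda epididymis).

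By DESeq2, SPTB and SPTA gave 8, diet in cauda epididymis 7, testis 21, liver 3, muscle 4 and blood 16, tRF 14, LNA 18, differences of diet effects 0 (testis) and 1 (cauda epididymis), and pi-Igf2bp1 turned to 1.40 in epididymosomes against cauda sperm. Scaled to the miRNA sum, diet gave 2 in testis, 2 in liver and 13 in muscle, tRF 1, and differences of diet effects 0 (caput sperm) and 0 (cauda epididymis). That scaling reversed Mir29a (0.48) and Mirlet7a (0.53) in cauda against caput sperm, though in caput sperm the sum is mostly let-7 itself. In caput sperm against testis it reversed Mir125b (-0.74), Mir181a (-1.01) and Mir30c (-0.055). In epididymosomes against cauda sperm it reversed Mirlet7a (-0.35) and Mir182 (-0.47). By library size alone, diet gave 1 in cauda epididymis, 2 in liver and 7 in muscle, and differences of diet effects 0 (caput sperm) and 0 (cauda epididymis). It reversed 10 features of epididymosomes against cauda epididymis: Mir125b (-0.48), Mir181a (-0.48), Mir871 (-0.63), tRNA-Met-CAT (-0.21), Mirlet7c (-0.56), tRNA-Gly-TCC (-0.27), Mir223 (-0.089), Mirlet7a (-0.42), Mir34c (-0.49) and tRNA-Gly-CCC (-0.35).

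With the library code as a replicate block, cauda sperm and testis gave 109 and the liver diet 1, the 3 differences of diet effects gave 0, 0 and 0, and Mir30b (-0.15), Mir192 (-0.15) and Mir143 (0.18) reversed in cauda sperm against testis. The libraries of that block without the block gave 142 for cauda sperm and testis and 216 for epididymosomes and cauda epididymis. For cauda sperm and testis the number and the make-up of the libraries changed together, since 4 of the 6 pairs hold the piRNA-rich libraries, matched to testis by the number of mice alone. The tRNA share lay 42.4 points higher in cauda sperm than in testis in those 6 pairs (6 of 6; exact sign-flip p over 3 codes = 0.25) and 22.8 points higher in cauda than in caput epididymis (10 of 10 pairs; exact sign-flip p over 5 codes = 0.0625), each the smallest possible, so neither test can pass. Cauda and caput epididymis gave 252 and epididymosomes and cauda epididymis 256 with the block. With control diet only, which leaves fewer samples, cauda and caput epididymis gave 79 and epididymosomes and cauda epididymis 175. Without the 4 piRNA-rich cauda sperm libraries, differences of diet effects were 0 for testis and 0 for cauda epididymis, and pi-Igf2bp1 turned to 0.67 in epididymosomes against cauda sperm. The tRNA share of cauda sperm then lay 23.4 points above caput sperm (adjusted p = 0.000611, exact permutation test). The 4 hold the lowest shares in cauda sperm, so that p-value decides nothing. Without pools the share of cauda epididymis lay 22.8 points above caput epididymis (adjusted p = 0.0475).

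When each library was left out in turn, diet in caput sperm and in cauda epididymis and both germ cell comparisons stayed at 0. In liver, muscle, blood and ES cells this leaves a single library in a group, so the counts there decide nothing and are not given. The share differences ranged from -11.3 to 10.99 for diet in caput sperm, -2.17 to 10.1 for diet in cauda epididymis, 4.44 to 9.62 for SPTA and spermatocytes and 2.97 to 15.02 for SPTB and SPTA. Of 100 simulated changes each of 2-fold and 4-fold, the self-test recovered 1 and 28 for tRF and GFP (2 per group), 0 and 0 for diet in caput sperm (4), 68 and 96 for SPTA and spermatocytes (4) and 75 and 96 for diet in testis (9). Each simulation changed 200 features and drew the noise of each feature on its own, without the structure that the splits above point to. So counts of 0 exclude little for tRF and GFP and for diet in caput sperm. In SPTA and spermatocytes and in testis they argue at most against as many changes of 4-fold under such noise, and say nothing on fewer changes.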

Other observations

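The similarity of whole profiles, the pooled gene sums and the libraries outside the comparisons, in this part, were looked at after the results above were seen, and no explanation is offered for them. The tRNA profile of cauda sperm was closest to that of cauda epididymosomes (r = 0.979, rho = 0.957 across 53 tRNA features), while its miRNA profile was closest to testis (r = 0.944, rho = 0.857 across 1013 miRNAs). Caput sperm was closest to caput epididymis in both tRNA (r = 0.974, rho = 0.926) and miRNA (r = 0.956, rho = 0.817). The miRNA profile of epididymosomes was closest to cauda epididymis (r = 0.968, rho = 0.844). These correlations run across features, which are not independent replicates.

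In the authors' pooled table, which has no replicates, epididymal secretory transcripts followed the segment. Gpx5 stood at 1419 RPM in caput epididymis, 1208 in caput sperm and 1.26 in cauda sperm, while Crisp1 stood at 726.6 in cauda epididymis, 300.5 in cauda sperm and 5.68 in caput sperm. The epididymal epithelium list summed to 967.6 in cauda epididymis, 364.3 in cauda sperm and 27.67 in epididymosomes. Spermatid transcripts such as Odf1 and Smcp, proteins of the sperm tail, stood at 22.67 and 18.28 in cauda sperm, 10.09 and 14.63 in testis and 1.11 and 1.02 in caput sperm. Hemoglobin transcripts reached 703.7 in blood and at most 14.58 elsewhere, and the seminal vesicle list at most 7.025. The Sertoli and Leydig list summed to 827.7 in caput sperm, 566.3 in caput epididymis and 26.37 in testis. In caput sperm almost all of it was Clu (821.6), so it does not mark testis cells there. Histone transcripts summed to 120.8 in caput epididymis and 31.5 in cauda sperm, ribosomal protein transcripts to 1982 in caput sperm and 408.8 in cauda sperm, and snoRNA and spliceosomal RNA to 2298 in caput epididymis and 1790 in cauda sperm.

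Libraries in no comparison held tRNA percentages without rRNA of 90.5 in the cauda sperm pool, 46.2, 94.9 and 95.7 in the 3 caput sperm libraries with no diet given, 91.3 in the high-fat epididymosome library and 90.4 and 63.0 in the 2 fusion libraries. Of the miRNA counts, the X-linked cluster took 4.05, 1.54 and 0.183% in those 3 caput sperm libraries, the first of which is named fusion. In the caput sperm libraries tested it took 0.025 to 0.144%. Let-7 took 11.1, 25.1 and 67.3% in the 3, against 53.6 to 83.5% in those tested. In ES cells the HiO2 and LoO2 libraries, 1 each, held 2516 and 45851 RPM of tRNA-Glu-CTC and 20182 and 52813 of tRNA-Gly-CCC. Within codes, testis also showed Mirlet7a lower on low protein in 8 of 9 codes, by -1.24 (exact sign-flip p = 0.0117), and tRNA-Gly-GCC higher in 8 of 9, by 0.67 (exact sign-flip p = 0.00781), both at an adjusted p of 0.0938 over 72 tests. The mean of the glycine tRNAs there was higher in 5 of 9, by 0.50 (exact sign-flip p = 0.109), and by 0.81 in 8 of 9 when set against the other tRNAs (exact sign-flip p = 0.0117); tRNA-Gly-TCC was higher in 7 of 9 and tRNA-Gly-CCC in 4 of 9. The let-7 mean was lower in 7 of 9, by -0.91 (exact sign-flip p = 0.0156). In cauda epididymis the glycine tRNAs were higher in 5 of 5 codes, by 0.94 (exact sign-flip p = 0.0625, the smallest possible), and let-7 lower in 4 of 5. In caput epididymis the glycine tRNAs were higher in 4 of 6, by 0.78, and let-7 lower in 5 of 6. In epididymosomes the mean of the glycine tRNAs was higher in 4 of 5, by 0.29, as were tRNA-Gly-CCC and tRNA-Gly-TCC, while tRNA-Gly-GCC was lower in 4 of 5 and let-7 higher in 3 of 5, by 0.62. In caput sperm the glycine tRNAs were higher in 2 of 4 and let-7 lower in 3 of 4.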
